A study of Mus musculus with 12 samples.

How the data were processed

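RNA was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The cells were dendritic cells grown from mouse bone marrow for 7 days in GM-CSF at 200 ng/ml and enriched with beads that bind CD11c. The labels give a purity above 95% and an input of 100 ng of total RNA. The arrays fall into 4 groups of 3: wild-type and IL-2 knockout cells, each left untreated or given curdlan for 6 h. All 12 arrays carry the strain label B6.129P2-Il2tm1Hor/J, the wild-type arrays too, so genotype was taken from the genotype label and the titles. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples.

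The deposited values are on the log2 scale, 1 value per probe set and array. The authors made them with RMA, per the labels, a method that corrects background, equalises the distributions of the arrays and summarises the probes of a transcript. The software version and which arrays were normalised together are not given in the sources used here. Array medians lay between 6.59 and 6.64, the lowest value was 2.76 and the highest was 14.04. Correlations between arrays across probe sets ranged from 0.981 to 0.997, and 0 pairs of arrays were identical. For arrays, the number of samples limits the precision.

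Of the 34760 probe sets in the table, 21640 carried exactly 1 gene symbol, 1321 carried several and 11799 were not listed in the probe table. Probe sets without exactly 1 symbol were left out because a change in them cannot be assigned to a gene. For the 954 genes with more than 1 such probe set, the one with the highest mean over all arrays was used, which gave 19937 genes. No further normalisation and no filter on dim genes were applied. Il2rg had no probe set with exactly 1 symbol and was not tested. Gene positions are from the mouse reference gene table.

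A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, which left 8 residual degrees of freedom. Its moderated test was two-sided. It gave 6 contrasts: the curdlan effect in each genotype, the genotype effect (knockout minus wild type) in untreated cells, in curdlan-treated cells and averaged over both, and the interaction (the curdlan effect in knockout cells minus that in wild-type cells). P-values were adjusted by the method of Benjamini and Hochberg over the genes tested within each contrast, and the threshold was an adjusted p of 0.05. SD is the standard deviation of the 3 arrays of a group. Standard errors (SE) of single genes are those of the fit. For a list or marker set, SE is the spread of its members over the square root of their number. It therefore carries no spread between cultures. The genes named in the text were fixed by rule: the disrupted gene Il2, its receptor genes and the curdlan receptor gene Clec7a; for each contrast, up to 10 genes with the largest rise and 10 with the largest fall among genes past the threshold whose arrays did not overlap between the groups, leaving out predicted genes and families the array cannot separate; and for each gene list, up to 4 members with the largest change past the threshold, or, where none passed, the 2 with the largest change.

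The contrasts were also tested on 40 gene lists with 867 members, of which 787 were tested and 80 had no usable probe set. The lists cover pathways, stress responses and marker genes of cell types. The test was limma's camera, which asks whether a list moves more than other genes, with a preset correlation of 0.01 between genes, adjusted over the 40 lists. It was repeated with the correlation estimated from the data, which is stricter here, and with fry, which tests each list on its own. Members past the threshold are given over all genes tested and adjusted over the list alone. The likeness of the responses of the genotypes is given as Pearson's r across genes, without a p-value, since genes are not independent replicates. Values of single lists or genes per culture were compared with exact permutation tests, two-sided, in which 3 against 3 cannot give a p below 0.1. The contrasts, gene lists, rules and most alternatives were chosen before the data were examined.

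The labels do not say that an untreated and a curdlan-treated array with the same number come from the same culture, so this was checked. After the group means were removed, same-numbered arrays correlated across genes at 0.45, 0.37 and 0.40 in wild-type cells and at 0.49, 0.53 and 0.60 in knockout cells, while pairs with different numbers within a genotype correlated between -0.48 and 0.06. Deviations from a group mean cancel within the group, so a high correlation of same-numbered pairs by itself lowers that of the others. Sex-linked genes matched in the same-numbered pairs. Between genotypes, each same-numbered pair of untreated arrays correlated at 0.11 or more, while 1 pair of treated arrays did not (-0.13), so the block for the replicate number is given beside the untreated comparison. Same-numbered arrays of a genotype are therefore treated as a shared culture in the alternatives and called a culture below, although the fit described above carries no block. A culture entered as a random block had a correlation of 0.261 (statmod 1.5.0).

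The alternatives were a random block and a fixed block for the culture, a block for the replicate number over all arrays, trend and robust moderation, array weights, quantile normalisation again, arrays centred on their medians, a filter on dim genes, the mean of a gene's probe sets, every single-gene probe set, a fit of only the arrays compared, a log2 fold change of at least 1 as well, the sex-linked level as a covariate, and each array and each culture left out in turn. The fit was tested on simulated arrays of 19937 genes with 3 arrays per group. Of 100 changed genes with a true log2 fold change of 1, it recovered 96 for the curdlan effect, 94 for the genotype effect in treated cells and 91 for the interaction; at 0.5 it recovered 77, 72 and 41. It made 8, 6 and 7 false calls, and 0 recovered genes had the wrong sign. The simulated noise was independent between genes and arrays, without the culture correlation of the data. The shares recovered therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.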

Results

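Gene expression was measured in dendritic cells grown from bone marrow of wild-type mice and mice lacking interleukin 2 (IL-2). Dendritic cells present antigen to T cells and make cytokines. Curdlan is a fungal-type beta-glucan that binds the receptor Dectin-1 (gene Clec7a). The design crossed genotype with 6 h of curdlan, and its stated purpose was to study what IL-2 signalling does in dendritic cells. Each of the 4 groups had 3 arrays, and all 12 arrays had alike distributions. The first principal component held 56.7% of the variance and the second 15.7%.

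The disrupted gene was measured first. Il2 lies on chromosome 3 between 37120713 and 37125954. Untreated wild-type cells gave log2 values of 5.56, 5.37 and 5.53 (mean 5.49 ± 0.11, SD, n = 3), and curdlan-treated wild-type cells gave 7.80, 7.22 and 6.74 (7.25 ± 0.53, SD, n = 3). Knockout cells gave 6.04, 5.88 and 5.77 untreated (5.90 ± 0.14, SD, n = 3) and 5.87, 5.80 and 5.63 with curdlan (5.77 ± 0.12, SD, n = 3). Il2 rose at least 3.4-fold with curdlan in wild-type cells (log2 fold change 1.77 ± 0.20, SE, adjusted p 0.000159) and did not pass in knockout cells (-0.13 ± 0.20, adjusted p 0.652). The fold is a lower bound, since the untreated wild-type values lay below those of every knockout array and below the median gene mean of 6.96. In curdlan-treated cells Il2 was lower in the knockout (-1.48 ± 0.20, adjusted p 0.0114), a difference that is also a lower bound in size, since the knockout values too lay below the median gene mean. In untreated cells the difference was 0.41 and did not pass (adjusted p 0.524). The call with curdlan was lost when only the arrays compared were fitted (adjusted p 0.085), without curdlan-treated wild-type array 2 (0.0538), and without knockout culture 3 (0.0568), wild-type culture 2 (0.0738) or knockout culture 2 (0.0779). Its adjusted p ranged from 0.00182 to 0.085 over the alternatives. The part of the gene that the probes cover relative to the deleted part is not given in the sources used here.

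**Figure D1:**
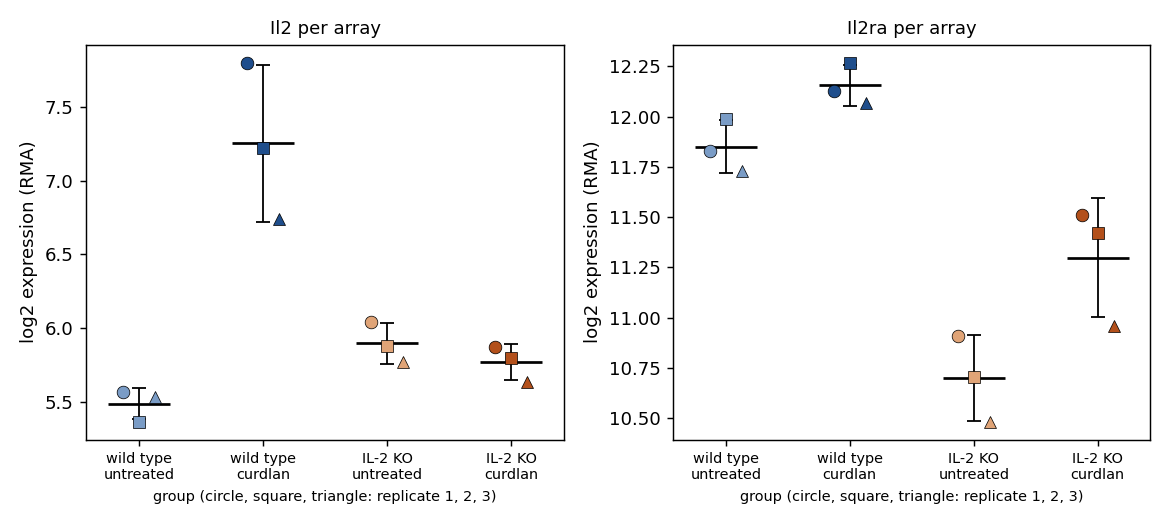
Log2 values of Il2 (left) and Il2ra (right) on each array (points), with group means (lines) and SD bars, n = 3 per group. Il2 reached 7.80, 7.22 and 6.74 in curdlan-treated wild-type cells and stayed at or under 6.04 on every other array.

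The receptor genes differed among themselves. Il2ra, which encodes the alpha chain of the IL-2 receptor (CD25), was lower in knockout cells. Its mean was 11.85 ± 0.13 (SD, n = 3) in untreated wild-type cells against 10.70 ± 0.21 (SD, n = 3) in untreated knockout cells, and 12.16 ± 0.10 against 11.30 ± 0.30 (SD, n = 3) with curdlan. The differences were -1.15 (adjusted p 0.00588) and -0.86 (adjusted p 0.026), with the 3 knockout arrays below the 3 wild-type arrays in each treatment. The difference in untreated cells lost its call without knockout culture 2 (0.0516). That with curdlan lost it when only the arrays compared were fitted (0.0888), without curdlan-treated wild-type arrays 2 (0.148) or 3 (0.0592), without curdlan-treated knockout arrays 2 (0.0765) or 3 (0.063), and without wild-type cultures 2 (0.146) or 3 (0.0948) or knockout culture 2 (0.116). Curdlan raised Il2ra in knockout cells (0.60, adjusted p 0.0132), while the change in wild-type cells did not pass (0.30, adjusted p 0.168). The knockout rise lost its call without knockout untreated array 3 (0.0531), curdlan-treated arrays 1 (0.055) or 2 (0.06) or cultures 1 (0.0539) or 2 (0.0824). Il2rb, the beta chain, rose with curdlan by 0.47 in wild-type cells (adjusted p 0.000847) and by 0.28 in knockout cells (adjusted p 0.0153) and did not pass by genotype (adjusted p 0.507 untreated, 0.858 with curdlan). Its untreated wild-type values (4.99 to 5.05) lay below the lower quartile of every array (5.08 to 5.15), near background, so the wild-type rise is a lower bound. The untreated knockout values were 5.08 to 5.24. Clec7a did not pass in any of these contrasts (adjusted p 0.662, 0.319, 0.379 and 0.943).

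The curdlan effect in wild-type cells shows what the treatment did when IL-2 could be made. Interferon-stimulated genes, which cells switch on after type I interferon, rose in all 28 measured, with the largest mean of the 40 lists. Inflammatory cytokine genes rose in 18 of 25, chemokine genes in 10 of 22 and maturation genes in 17 of 24. The C-type lectin genes Cd209a and Cd209c and 32 of 36 cell cycle genes fell. The largest rises were in Ifit3b (at least 21.7-fold, from 4.52 ± 0.15 to 8.96 ± 0.10, SD, n = 3, adjusted p 1.53e-06), Ifit2 (log2 fold change 4.21, adjusted p 1.14e-07) and Il12b, which encodes the p40 chain of IL-12 (18-fold, from 7.24 ± 0.32 to 11.41 ± 0.30, adjusted p 0.00011). Next came Ifi205 (4.05), Ifi213 (3.84), Slfn4 (3.84), Ifit3 (3.77), Cxcl10 (3.71), Oasl1 (3.62) and Ifit1 (3.60), with adjusted p at or under 3.8e-05. Untreated Ifit3b lay below the lower quartile of every array (5.08 to 5.15), near background, so its fold is a lower bound. The largest falls were in Cd209a, the mouse DC-SIGN gene (-2.87, from 11.14 ± 0.36 to 8.27 ± 0.10, adjusted p 3.87e-05), Cd209c (-2.42, adjusted p 0.000321), the sodium-proton exchanger gene Slc9a9 (-1.93, adjusted p 3.06e-06) and the LIF receptor gene Lifr (-1.57, adjusted p 0.000723). Ncapg, Neil3, Anln, Depdc1a and Knl1 fell by 1.49, 1.48, 1.44, 1.42 and 1.41.

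Among the gene lists in wild-type cells, all 28 interferon-stimulated genes rose (mean 2.36, camera adjusted p 4.5e-41, adjusted p = 0.112 with an estimated correlation; 28 adjusted over the list alone). Of 36 cell cycle genes, 32 fell (34 adjusted over the list alone, mean -0.83, camera adjusted p 1.31e-16, adjusted p = 0.315 with an estimated correlation), among them Kif11 (-1.40), Bub1 (-1.26), Kif20a (-1.17) and Plk1 (-1.16). NF-kB targets rose in 19 of 27 (25 adjusted over the list alone, camera adjusted p 6.99e-16, adjusted p = 0.112 with an estimated correlation), led by the cyclooxygenase gene Ptgs2 (2.86), Cd40 (2.37), Traf1 (1.09) and Nfkbiz (1.07). Of 25 inflammatory cytokine genes 18 rose (19 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation), with Il6 at 2.71, Edn1 at 1.97 and Il1b at 1.67. Of 22 chemokine genes 10 rose (11 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation), including Cxcl9 (adjusted p 0.00753), Cxcl2 (2.00) and Ccl12 (1.61). Maturation genes rose in 17 of 24 and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation), with Tnfsf4 at 1.83, Cd70 at 1.64 and Il15ra at 1.58.

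IL-2 and common gamma chain signalling genes rose in 10 of 19 and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p 1.34e-06, adjusted p = 0.112 with an estimated correlation). Besides Il2, Il15 rose by 1.71 and the transcription factor gene Stat5a by 1.21. STAT5-induced genes rose in 10 of 21 and fell in 1 (11 and 2 adjusted over the list alone, adjusted p = 0.376 with an estimated correlation), with Lta at 1.27, Socs3 at 1.22, Ccnd1 at 1.00 and Osm at 0.86. Calcineurin-NFAT targets rose in 8 of 19 and fell in 2 (10 and 2 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation), among them Cd83 (1.28) and Nr4a3 (1.26). Of the Dectin-1 pathway genes 5 of 23 rose and 4 fell (6 and 5 adjusted over the list alone) and camera did not call the list (adjusted p 0.433), while fry, which tests a list on its own, did (mean 0.10, adjusted p 0.0132). Clec4e (Mincle) rose by 1.39 and Card9 fell by 0.71. In presentation genes, 6 of 21 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p 0.186; list median -0.02 and mean 0.24 had opposite signs), with Nlrc5 at 1.81 and Tap1 at 1.21. Oxidative phosphorylation genes fell in 6 of 29 (16 adjusted over the list alone, adjusted p = 0.376 with an estimated correlation), such as Ndufs1 (-0.42). Cholesterol synthesis genes fell in 6 of 20 and rose in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.589 with an estimated correlation), such as Dhcr7 (-0.66). The list call was lost without wild-type curdlan-treated array 1 (0.0512). In 2 lists kept as signs of RNA handling and quality, immediate early genes rose in 7 of 21 and fell in 1 (8 and 2 adjusted over the list alone, camera adjusted p 0.0145, adjusted p = 0.431 with an estimated correlation), with Dusp1 at 0.90 and Maff at 0.73. Ribosomal protein genes were lower as a list (mean -0.08, camera adjusted p 0.027, adjusted p = 0.407 with an estimated correlation) with 0 of 21 past the threshold over all genes or over the list alone. The first call was lost without wild-type untreated array 2 (0.0621), and the second without wild-type untreated array 2 (0.0709), curdlan-treated array 1 (0.0879), culture 1 (0.071) or culture 3 (0.0596).

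Cell death genes were examined because the series title concerns apoptosis of mature cells. In wild-type cells given curdlan, pro-apoptotic genes did not move more than other genes (camera adjusted p 0.343) but rose on their own by fry (mean 0.14, adjusted p 0.0125; 5 of 31 rose and 2 fell, 5 and 2 adjusted over the list alone). The death ligand gene Tnfsf10 (TRAIL) rose by 3.35 (adjusted p 6.4e-05) and Fas by 0.91 (adjusted p 0.000308), while Casp6 fell by 0.72 (adjusted p 0.000197). Tnfsf10 alone made up most of the net rise of the pro-apoptotic list. Anti-apoptotic genes rose in 9 of 22 and fell in 2 (10 and 2 adjusted over the list alone, camera adjusted p 0.00938, adjusted p = 0.112 with an estimated correlation), with Gadd45b at 1.45, Cflar at 1.14 and Tnfaip3 at 1.04. Birc5 (survivin) fell by 1.06. Pyroptosis and necroptosis genes rose in 7 of 15 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation), with Zbp1 at 2.02 and Casp4 at 1.86, against Nlrp1b at -1.24.

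In all, 3899 of 19937 genes passed in wild-type cells, 1449 higher and 2450 lower with curdlan. Over all genes, the 3 treated arrays did not overlap the 3 untreated in 38% (chance gives 10%). Camera called 15 lists, 11 up and 4 down. Leaving out a wild-type culture lowered the gene count to 1841 (culture 1), 1959 (culture 2) and 2202 (culture 3). Of the 125 genes that the naming rule gave in this contrast, 87, Ifit3b, Il12b, Il2 and Cd209a among them, kept their call with each array and each culture left out.

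In IL-2 knockout cells the same contrast asks what curdlan did without IL-2. Interferon-stimulated genes rose in all 28 measured, and the nitric oxide synthase gene Nos2 and the cyclooxygenase gene Ptgs2 were among the largest rises. Cd209a, Cd209c and 27 of 36 cell cycle genes fell. Ifit2 rose by 3.79 (adjusted p 5.13e-07) and Nos2 by at least 3.74 (adjusted p 0.000343, 5.99 untreated, 9.73 ± 1.30 with curdlan, SD, n = 3). The Nos2 rise is a lower bound, since its untreated mean lay below the median gene mean of 6.96. Ms4a4c rose by 3.74 (adjusted p 2.37e-05), Ifit3b by 3.68 (at least 12.8-fold from an untreated 5.08, adjusted p 1.03e-05) and Cxcl10 by 3.63 (adjusted p 5.54e-05). Tnfsf10 (3.34), Ptgs2 (3.33), Slfn4 (3.33), Ifit3 (3.23) and the GTPase gene Iigp1 (3.22) followed. Il12b rose 8.83-fold (adjusted p 0.000882). Cd209a fell by 1.84 (adjusted p 0.000979), Dkc1 by 1.42 (adjusted p 0.000199), Anln by 1.39, Scel by 1.31, Cd209c by 1.31, Ccna2 by 1.31, the potassium channel gene Kcnn3 by 1.30, and Rgs18 and Klrb1b by 1.28 each.

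All 28 interferon-stimulated genes rose in knockout cells (mean 2.09, camera adjusted p 2.73e-33, adjusted p = 0.178 with an estimated correlation; 28 adjusted over the list alone), Isg20 by 3.21. NF-kB targets rose in 19 of 27 (24 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), Cd40 by 2.92 and Traf1 by 1.24. Cytokine genes rose in 18 of 25 (19 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), Il6 by at least 2.29 from an untreated 5.10, Edn1 by 1.60 and Il1b by 1.38. Chemokine genes rose in 11 of 22 (11 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), Cxcl9 by 1.91 and Cxcl2 by 1.73. Maturation genes rose in 15 of 24 (17 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), including Tnfsf4 (1.66) and the actin-bundling gene Fscn1 (1.64). Cell cycle genes fell in 27 of 36 (32 adjusted over the list alone, mean -0.67, adjusted p = 0.414 with an estimated correlation), among them Kif11 (-1.21), Top2a (-1.16) and Rrm2 (-1.13).

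Il15ra rose by 1.75, Il15 by 1.68 and Stat5a by 1.04 in knockout cells, within a signalling list in which 10 of 19 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.355 with an estimated correlation). STAT5-induced genes rose in 9 of 21 and fell in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.43 with an estimated correlation), with Lta at 1.08, Socs3 at 1.03 and Ccnd2 at 0.93. Calcineurin-NFAT targets rose in 7 of 19 and fell in 2 (7 and 2 adjusted over the list alone), with Nr4a3 at 1.49 and Cd83 at 1.40, and did not pass as a list (camera adjusted p 0.0724). Of 14 stroma and fibroblast markers 3 rose (4 adjusted over the list alone, mean 0.27, camera adjusted p 0.0237, adjusted p = 0.455 with an estimated correlation): Kdr (1.54), Cdh5 (adjusted p 0.00463) and Col1a2 (0.31). That list missed the threshold in wild-type cells (mean 0.23, camera adjusted p 0.0585) and lost its call in knockout cells without culture 1 (0.0537). Oxidative phosphorylation genes fell in 11 of 29 (15 adjusted over the list alone, adjusted p = 0.355 with an estimated correlation), Ndufb5 by 0.32. Cholesterol synthesis genes fell in 9 of 20 (12 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation), Dhcr7 by 0.72 and Stard4 by 0.49. Ribosomal protein genes fell in 5 of 21 (5 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), Rpl5 by 0.36. In the p53 target list 9 of 16 fell and 2 rose (10 and 3 adjusted over the list alone, adjusted p = 0.43 with an estimated correlation), with Sesn1 at -0.97, Zmat3 at -0.85 and Fas at 0.80. Pyroptosis genes rose in 7 of 15 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), Zbp1 by 1.80. The pro-apoptotic list (mean 0.12) passed neither camera (adjusted p 0.737) nor fry (adjusted p 0.0723), although it was higher on each treated than on each untreated array. Most of its net rise came from Tnfsf10 alone. The anti-apoptotic list (mean 0.22) missed the threshold of camera (adjusted p 0.0581) and passed fry (adjusted p 1.7e-05). Gadd45b rose by 1.48 and Cflar by 1.13.

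The knockout count was 4481 genes, 1853 higher and 2628 lower, and camera called 14 lists, 9 up and 5 down. Over all genes, the arrays did not overlap in 40.3% (chance gives 10%). With a random culture block 6699 passed, 3080 higher and 3619 lower. The gene count fell to 2041 without curdlan-treated array 2, 2227 without untreated array 1, 2673 without curdlan-treated array 1, 2688 without untreated array 3, 1079 without culture 1 and 2590 without culture 2, all knockout arrays. Of 134 genes given by the naming rule, 67, Ifit2, Nos2, Il12b and Cd209a among them, kept their call with each array and each culture left out.

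Set side by side, the curdlan responses of the genotypes were alike across genes. Pearson's r across all genes was 0.92 (Spearman's rho 0.827), and genes are not independent replicates. The slope of the knockout on the wild-type response was 0.885. Past the threshold in both genotypes, 1035 genes such as Ifit2, Ifit3 and Cxcl10 were higher, 1923 such as Cd209a, Cd209c and Anln were lower, and 0 went opposite ways, where independent lists would share 134.7 and 322.9. Of the 5422 genes past the threshold in either genotype, 97.8% moved the same way.

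**Figure D2:**
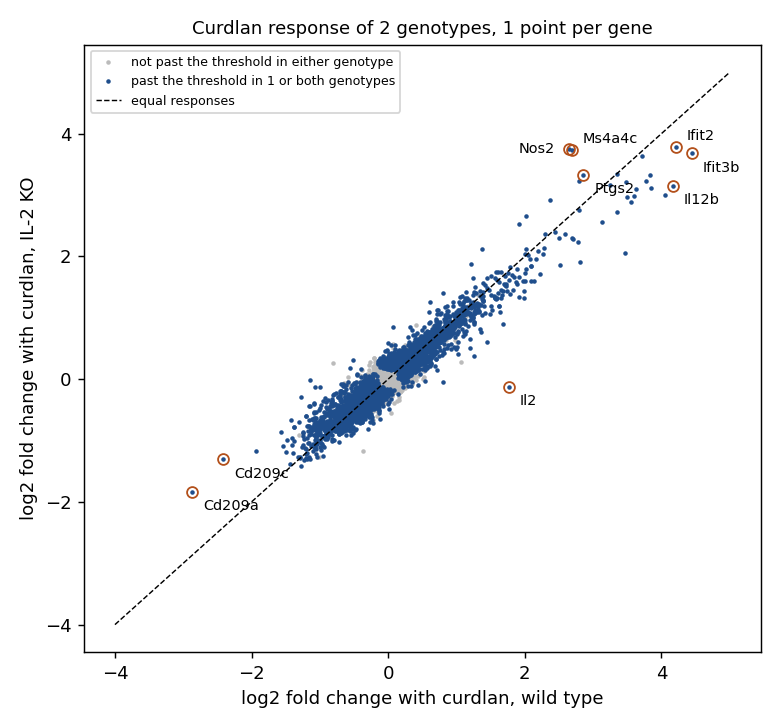
Log2 fold change with curdlan in wild-type cells (x axis) against knockout cells (y axis), 1 point per gene, with a line of equal responses. Il2 sits apart, at 1.77 and -0.13, while Ifit2, Ifit3b, Il12b, Cd209a and Cd209c changed in the same direction in both.

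The interaction asks whether the response to curdlan differed between the genotypes. In limma's test 0 genes passed, and 552 had an unadjusted p under 0.05. Il2 did not pass: its response differed by -1.89 ± 0.28 (SE, a lower bound in size; adjusted p 0.357; exact permutation p 0.1, the smallest possible). With a random culture block its adjusted p was 0.058, and over all alternatives it ranged from 0.0113 to 1. Il2 passed without curdlan-treated wild-type array 1 (adjusted p 0.0338), without curdlan-treated wild-type array 3 (adjusted p 0.0113) and without wild-type culture 3 (adjusted p 0.0286). The count over all genes was then 2, 2 and 3, and it was 1 without untreated knockout array 1. Cd209a (1.03), Il12b (-1.03), Ms4a4c (1.05) and Cxcl9 (-0.89) had the largest differences in their lists and did not pass (adjusted p 1 each).

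Camera called 8 lists in the interaction, with 0 members past the threshold over all genes. Interferon-stimulated genes rose less in knockout than in wild-type cells (mean -0.27, camera adjusted p 1.37e-11, adjusted p = 0.805 with an estimated correlation; 1 lower adjusted over the list alone). The mean was -0.11 without knockout curdlan-treated array 3, -0.16 without knockout untreated array 2 and -0.15 without knockout culture 3, with the camera call kept throughout. Cholesterol synthesis, NRF2 targets, IL-2 signalling, inflammatory cytokines, immediate early genes and ribosomal proteins were lower and the cell cycle list was higher, and each of these 7 lists lost its call without at least 1 array. Without knockout curdlan-treated array 2 the adjusted p was 0.185 for cholesterol synthesis, NRF2 targets and ribosomal proteins. Without knockout curdlan-treated array 3 it was 0.143 for IL-2 signalling and for immediate early genes, 0.558 for cytokines and 0.649 for the cell cycle. Without wild-type untreated array 2 it was 0.913 for the cell cycle. The sign of the cell cycle list reversed with array weights (-0.096). For these calls, adjusted p = 0.863 with an estimated correlation for the cell cycle and 0.805 for the others. By fry 0 lists passed; 9 had an unadjusted camera p under 0.05. The list count was 4 without untreated wild-type array 2 and 5 without knockout curdlan-treated array 2, knockout untreated array 1, wild-type curdlan-treated array 1 or wild-type culture 2.

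The genotype effect in untreated cells asks how the genotypes differed before any stimulus. In knockout cells 18 of 36 cell cycle genes and 2 of 17 conventional dendritic cell markers were lower, and 4 of 28 interferon-stimulated genes were higher. Of 11 monocyte markers 2 were lower, Ifitm6 and Treml4 (3 adjusted over the list alone), and the list did not pass (mean -0.25, camera adjusted p 0.443). These 2 falls together exceed the fall of the whole list, so the other monocyte markers were on average not lower. T cell, B cell and NK cell lists did not pass either (camera adjusted p 0.398, 0.638 and 0.751). The means of the monocyte, plasmacytoid, eosinophil, mast cell and neutrophil lists lay below the wild-type arrays on each untreated knockout array. For the last 4 the mean differences were -0.17, -0.20, -0.13 and -0.11, without a call (camera adjusted p 0.591, 0.317, 0.507 and 0.565; 1 of 10, 1 of 8, 0 of 15 and 0 of 18 lower over all genes, and 2, 1, 1 and 0 adjusted over the list alone). Lowest against wild type were Cd209a (-2.45, 11.14 ± 0.36 against 8.69 ± 0.60, SD, n = 3, adjusted p 0.00588), Ifitm6, a monocyte marker (-2.15, 8.44 ± 0.35 against 6.29 ± 0.87, SD, n = 3, adjusted p 0.018), and Cd209c (-1.77, adjusted p 0.0176). The Ifitm6 difference is a lower bound in size, since its knockout mean lay below the median gene mean of 6.96. Next were Tespa1 (-1.70, adjusted p 0.0156), Gimap5 (-1.58, adjusted p 0.0149), the transcription factor gene Spib (-1.52, adjusted p 0.0159), Adam23 (-1.51, adjusted p 0.00588), the cyclin gene Ccnb2 (-1.50, adjusted p 0.0173), Treml4 (-1.49, adjusted p 0.0305) and Ehf (-1.46, adjusted p 0.00588). Highest were the scavenger receptor gene Scarf1 (1.21, 8.14 ± 0.14 against 9.35 ± 0.15, SD, n = 3, adjusted p 0.000587), Ifi205 (0.97, adjusted p 0.0306) and Phf11d (0.96, adjusted p 0.0113). Smaller rises were in Tmeff1 (0.84, adjusted p 0.00918), the Notch ligand gene Jag1 (0.83, adjusted p 0.008), Rtp4 (0.76, adjusted p 0.0345), Slfn8 (0.76, adjusted p 0.0128), Pltp (0.67, adjusted p 0.0392) and Ifit1 (0.65, adjusted p 0.0437).

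Of 36 cell cycle genes 18 were lower in untreated knockout cells (33 adjusted over the list alone, mean -0.84, camera adjusted p 8.92e-39, adjusted p = 0.288 with an estimated correlation), among them Kif11 (-1.44), Plk1 (-1.37) and Bub1 (-1.35). Conventional dendritic cell markers were lower as a list (mean -0.46, camera adjusted p 1.27e-05; adjusted p 0.0322 with an estimated correlation; 2 of 17 past the threshold, 8 lower and 1 higher adjusted over the list alone), through Cd209a and Dpp4 (-1.45). Interferon-stimulated genes were higher in 4 of 28 (12 adjusted over the list alone, mean 0.30, camera adjusted p 3.45e-10, adjusted p = 0.724 with an estimated correlation): Rtp4, Ifit1, Oasl2 (0.59) and Rsad2 (0.51). Without knockout untreated array 2 or knockout culture 2 the mean of this list was 0.19. Maturation genes were lower in 3 of 24 (9 adjusted over the list alone, adjusted p = 0.657 with an estimated correlation): Fscn1 (-0.60), Icosl (-0.46) and Tnfrsf9 (-0.44). Cholesterol synthesis genes were lower as a list with 0 members past the threshold over all genes or over the list alone (camera adjusted p 2.69e-06, adjusted p = 0.724 with an estimated correlation). The pattern receptor list was called up by camera with a median of 0.14 and a mean of 0.03 (adjusted p = 0.724 with an estimated correlation; 1 of 28 lower, 6 higher and 3 lower adjusted over the list alone). Its mean was -0.007 without wild-type untreated array 3 or culture 3, -0.001 without wild-type untreated array 2 or culture 2, and 0.09 without wild-type untreated array 1 or culture 1. It was 0.004 without knockout untreated array 1 or culture 1 and 0.06 without knockout untreated array 2 or culture 2, and the call was lost without wild-type untreated array 2 (0.106) or knockout untreated array 3 (0.126) and without wild-type culture 2 (0.115) or 3 (0.063). Lysosome genes were higher (adjusted p = 0.768 with an estimated correlation; 1 of 24 over all genes and over the list alone, Npc2 at 0.34). They lost the call without wild-type untreated array 2 (0.0591), knockout untreated array 3 (0.2), wild-type culture 2 (0.0744) or knockout culture 3 (0.172). NF-kB targets were lower (adjusted p = 0.822 with an estimated correlation) with 0 of 27 past the threshold over all genes and 2 adjusted over the list alone. Their call was lost without wild-type untreated array 3 (0.295) or culture 3 (0.301) or knockout untreated array 1 (0.0534), and with a block for the replicate number (0.0535).

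Among death genes in untreated knockout cells, Pmaip1 (Noxa) was lower by -0.55 (adjusted p 0.0139) and Birc5 by -1.15 (adjusted p 0.017), while the pro-apoptotic and anti-apoptotic lists were not called (camera adjusted p 0.85 and 0.884, fry adjusted p 0.94 and 0.811). The anti-apoptotic mean was 9.54 to 9.57 on the knockout and 9.60 to 9.62 on the wild-type arrays. Birc5 alone made up most of this difference. The presentation gene H2-Oa (-1.04, adjusted p 0.0367), the lipoxygenase gene Alox15 (adjusted p 0.00888) and Klrd1 (-0.53, adjusted p 0.0383) were lower too. Untreated cells gave 283 genes by genotype, 46 higher and 237 lower in the knockout, and 8 lists, 3 up and 5 down. Over all genes, the arrays of the groups did not overlap in 15.4% (chance gives 10%). A block for the replicate number over all arrays gave 699 genes. The count was 52 without wild-type untreated array 2, 81 without knockout untreated array 2, 111 without knockout untreated array 1, 134 without wild-type untreated array 3, 166 without knockout curdlan-treated array 1 and 447 without wild-type untreated array 1. With cultures left out it was 9 without knockout culture 2, 60 without knockout culture 1, 78 without wild-type culture 3, 122 without wild-type culture 2 and 608 without wild-type culture 1. Of 36 genes given by the naming rule, Scarf1 and Adam23 kept their call with each array and each culture left out. When only the arrays compared were fitted, 26 of the 36 lost it. With the sex-linked level as a covariate 13, among them Ifi205, Rtp4, Ifit1, Oasl2, Rsad2, Treml4, Fscn1 and H2-Oa, lost it.

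With curdlan, the same comparison asks what differed once Il2 mRNA had risen in wild-type cells. In the knockout 6 of 36 cell cycle genes and 2 of 17 conventional dendritic cell markers were lower. The monocyte markers Ifitm6 and Treml4 were lower, 2 of 11 (2 adjusted over the list alone), without a call for their list (mean -0.24, camera adjusted p 0.0909). Together their falls exceed that of the whole list, so the other monocyte markers were on average not lower. The plasmacytoid and mast cell means lay below the wild-type arrays on each treated knockout array (differences of -0.12 and -0.09), without a call (camera adjusted p 0.712 and 0.845; 0 of 10 and 0 of 15 lower over all genes, 2 and 0 adjusted over the list alone). Pik3r1, a subunit of the PI3 kinase that acts downstream of cytokine receptors, joined Il2 and Il2ra. Ifitm6 (-2.04, adjusted p 0.035), Treml4 (-1.54, adjusted p 0.0388), Tespa1 (-1.52, adjusted p 0.036), the integrin gene Itgb8 (-1.47, adjusted p 0.0345), Cd209a (-1.42, adjusted p 0.0396), H2ac4 (-1.29, adjusted p 0.036), Top2a (-1.27, adjusted p 0.0426), Plk1 (-1.25, adjusted p 0.036) and Ccna2 (-1.24, adjusted p 0.032) were lowest besides Il2. Scarf1 (1.04, adjusted p 0.0028), the complement gene C2 (1.03, adjusted p 0.00704), the serotonin receptor gene Htr2b (0.89, adjusted p 0.00493), Tmeff1 (0.88, adjusted p 0.0124), Airn (0.64, adjusted p 0.032), Lat (0.62, adjusted p 0.0426), Nbas (0.59, adjusted p 0.00337) and the lectin gene Clec12a (0.58, adjusted p 0.0429) were highest.

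In treated cells 6 of 36 cell cycle genes were lower (30 adjusted over the list alone, mean -0.69, camera adjusted p 7.93e-30, adjusted p = 0.252 with an estimated correlation), Prc1 by -1.10. Cholesterol synthesis genes were lower in 2 of 20 (13 adjusted over the list alone, mean -0.24, camera adjusted p 3.92e-14, adjusted p = 0.252 with an estimated correlation): Idi1 (-0.50) and Hmgcs1 (-0.34). Conventional dendritic cell markers were lower (mean -0.33, camera adjusted p 5.99e-05, adjusted p = 0.0525 with an estimated correlation; 2 of 17, 3 adjusted over the list alone), Dpp4 by -1.20. IL-2 signalling genes were lower in 3 of 19 (7 adjusted over the list alone, adjusted p = 0.252 with an estimated correlation): Il2, Il2ra and Pik3r1 (-0.46). The list holds the disrupted gene Il2, so part of this fall was fixed by the design. STAT5-induced genes were lower in 1 of 21, Il2ra (3 adjusted over the list alone, adjusted p = 0.561 with an estimated correlation). Their call was lost without knockout curdlan-treated array 3 (0.115) or culture 3 (0.138). Maturation genes were lower in 1 of 24 (5 adjusted over the list alone, adjusted p = 0.252 with an estimated correlation), the 4-1BB ligand gene Tnfsf9 (-0.64). Ribosomal protein genes were lower as a list (mean -0.10, adjusted p = 0.223 with an estimated correlation) with 0 of 21 past the threshold over all genes or over the list alone. Pattern receptors were called up (adjusted p = 0.561 with an estimated correlation; 1 of 28 higher and 1 lower, 5 and 1 adjusted over the list alone). Their mean of 0.09 became 0.13 without knockout curdlan-treated array 3 or culture 3, and their call was lost without knockout culture 2 (0.0562). Camera did not call interferon-stimulated genes (mean 0.03, adjusted p 0.906) or the pro-apoptotic list (mean -0.02, adjusted p 0.485).

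Treated cells gave 124 genes by genotype, 21 higher and 103 lower in the knockout, and 8 lists, 1 up and 7 down. Over all genes, the arrays did not overlap in 14.6% (chance gives 10%). The gene count was 19 without wild-type curdlan-treated array 2, 29 without knockout curdlan-treated array 2, 35 without knockout curdlan-treated array 3, 43 without wild-type curdlan-treated array 3, 53 without knockout curdlan-treated array 1 and 80 without wild-type untreated array 3. For cultures it was 18 without wild-type culture 3, 19 without knockout culture 2, 29 without wild-type culture 2, 42 without knockout culture 3, 54 without knockout culture 1 and 299 without wild-type culture 1. The list count was 15 without knockout curdlan-treated array 1 and 13 without knockout culture 1. Of 27 genes given by the naming rule, Scarf1, Htr2b and Nbas kept their call with each array and each culture left out. When only the arrays compared were fitted, 23 of the 27 lost it. With the sex-linked level as a covariate 13, among them Ifitm6, Treml4, Top2a, Plk1, Ccna2 and Dpp4, lost it.

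Averaged over treatments, the genotype effect uses all 12 arrays. In knockout cells 29 of 36 cell cycle genes, 7 of 17 conventional dendritic cell markers and the stem cell antigen gene Cd34 were lower. Of 11 monocyte markers 2 were lower (2 adjusted over the list alone) and the list (mean -0.25) did not pass camera (adjusted p 0.217) but passed fry (adjusted p 0.0186). The 2, Ifitm6 and Treml4, fell by more together than the whole list, so its other markers were on average not lower. Ifitm6 (-2.10, adjusted p 0.00148), Cd209a (-1.94, adjusted p 0.000579), Tespa1 (-1.61, adjusted p 0.00136), Treml4 (-1.51, adjusted p 0.00196), Cd34 (-1.42, adjusted p 0.00619), Ccnb2 (-1.38, adjusted p 0.00186), Spib (-1.35, adjusted p 0.00186), Kif11 (-1.34, adjusted p 0.00249) and Dpp4 (-1.33, adjusted p 0.00132) were lowest. Scarf1 (1.12, adjusted p 2.8e-05), Tmeff1 (0.86, adjusted p 0.000579), C2 (0.79, adjusted p 0.00104), Htr2b (0.73, adjusted p 0.000579), the acute phase gene Saa3 (0.73, adjusted p 0.0291), Jag1 (0.63, adjusted p 0.00148), Phf11d (0.63, adjusted p 0.00446), Pltp (0.61, adjusted p 0.00477) and Batf2 (0.57, adjusted p 0.00629) were highest. Iigp1 was higher too (1.04, adjusted p 0.0367), a call lost with a random culture block (adjusted p 0.0558, range over all alternatives up to 0.166).

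In the averaged contrast 29 of 36 cell cycle genes were lower (33 adjusted over the list alone, mean -0.76, camera adjusted p 2.09e-38, adjusted p = 0.258 with an estimated correlation), such as Plk1 (-1.31) and Bub1 (-1.27). Conventional dendritic cell markers were lower in 7 of 17 (9 lower and 1 higher adjusted over the list alone, mean -0.40; adjusted p 0.024 with an estimated correlation), such as the integrin gene Itgae, CD103 (-1.03), and Kmo (-0.99). Cholesterol synthesis genes were lower in 6 of 20 (16 adjusted over the list alone, mean -0.19, adjusted p = 0.258 with an estimated correlation), such as Idi1 (-0.36), Hmgcs1 (-0.27) and Stard4 (-0.26). Maturation genes were lower in 8 of 24 (15 lower and 1 higher adjusted over the list alone, adjusted p = 0.258 with an estimated correlation), such as Tnfsf9 (-0.48) and Relb (-0.46). STAT5-induced genes were lower in 4 of 21 (4 adjusted over the list alone, adjusted p = 0.65 with an estimated correlation): Il2ra, Tnfrsf4 (OX40, -0.91), Tnfrsf18 (GITR, -0.69) and Ccnd2 (-0.52). This call was lost without knockout untreated array 3 (0.0545), curdlan-treated array 3 (0.0807) or culture 3 (0.338), or wild-type culture 1 (0.125). IL-2 signalling genes were lower in 5 of 19 (6 adjusted over the list alone, adjusted p = 0.595 with an estimated correlation), including Jak2 (-0.43) and Pik3r1 (-0.32). They lost the call without knockout culture 1 (0.0602) or 3 (0.0711), and their list holds the disrupted gene Il2. NF-kB targets were lower in 4 of 27 (8 adjusted over the list alone, adjusted p = 0.817 with an estimated correlation), including Traf1 (-0.53) and Rel (-0.34). Their call was lost without wild-type untreated array 3 (0.0779), wild-type curdlan-treated array 1 (0.0939), knockout curdlan-treated array 3 (0.211) or knockout culture 3 (0.237). Pattern receptors were higher in 5 of 28 and lower in 1 (13 and 4 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation), including Clec12a (0.52) and Fcgr2b (0.32). Their list mean of 0.06 was 0.03 without wild-type culture 3 or knockout culture 1, 0.04 without wild-type culture 2, 0.09 without wild-type untreated array 1 and 0.10 without wild-type culture 1. Ribosomal protein genes were lower as a list (mean -0.07, camera adjusted p 0.000118, adjusted p = 0.258 with an estimated correlation; 1 of 21 over all genes and over the list alone, Rps20 at adjusted p 0.0281). Lysosome genes were higher in 2 of 24 (5 higher and 1 lower adjusted over the list alone, camera adjusted p 0.017, adjusted p = 0.65 with an estimated correlation), Npc2 (0.28) and Atp6v1h (0.16). The lysosome call was lost without wild-type curdlan-treated array 1 (0.0939), knockout untreated array 3 (0.0945), knockout curdlan-treated array 3 (0.206), wild-type culture 1 (0.116) or knockout culture 3 (0.409). Interferon-stimulated genes were higher in 1 of 28, Rtp4 at 0.48 (6 adjusted over the list alone, adjusted p = 0.817 with an estimated correlation). The list mean of 0.17 was 0.11 without knockout untreated array 2 and 0.10 without knockout curdlan-treated array 2. It was 0.27 without knockout culture 3, and without knockout culture 2 the call was lost (mean 0.05, adjusted p 0.121).

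Pmaip1 (-0.49, adjusted p 0.00148), the BH3-only gene Bmf (-0.50, adjusted p 0.00791) and Birc5 (-0.89, adjusted p 0.00412) were lower in knockout cells averaged over treatments. Neither the pro-apoptotic nor the anti-apoptotic list was called (camera adjusted p 0.88 and 0.726, fry adjusted p 0.834 and 0.468). In both treatments the anti-apoptotic mean was lower on every knockout than on every wild-type array (averaged difference -0.06). Birc5 alone made up most of this averaged difference. The average gave 1005 genes, 296 higher and 709 lower, and 11 lists, 3 up and 8 down. The same cultures enter both treatments, so these arrays are not independent; with a random culture block 682 genes passed, 149 higher and 533 lower. The gene count was 536 without wild-type curdlan-treated array 2, 594 without wild-type untreated array 2, 659 without wild-type untreated array 3, 325 without wild-type culture 2, 473 without wild-type culture 3, 494 without knockout culture 1 and 591 without knockout culture 2, and the list count was 7 without knockout culture 3. Of 74 genes given by the naming rule, 25, among them Scarf1, Il2ra, Cd209a, Ifitm6, Dpp4, Ccnb2 and Pmaip1, kept their call with each array and each culture left out. With the sex-linked level as a covariate 22, among them Saa3 and Rtp4, lost it. Past the threshold in both treatments were 9 higher genes, such as Scarf1 and Tmeff1, and 55 lower genes, such as Cd209a and Plk1. The treatments share their cultures, so this overlap has no baseline of independent lists.

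**Figure D3:**
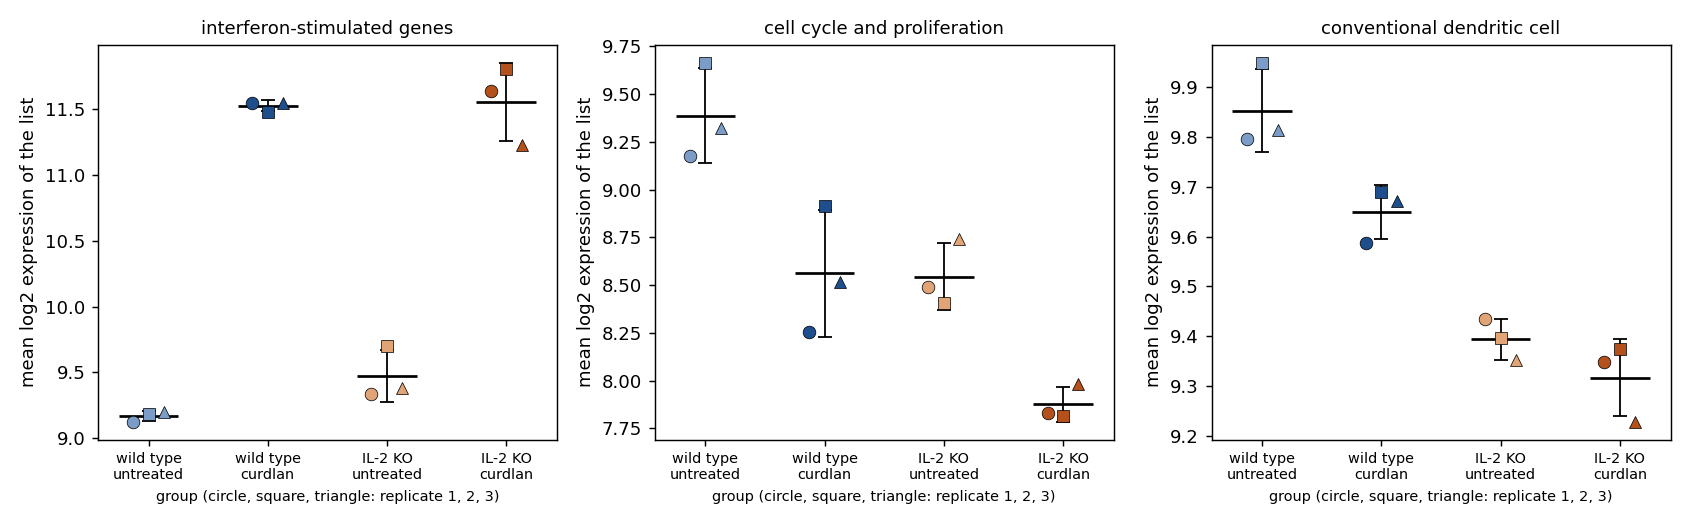
Mean log2 value of the interferon-stimulated, cell cycle and conventional dendritic cell lists on each array (points), with group means (lines) and SD bars, n = 3 per group. Interferon-stimulated genes averaged 9.17 in untreated wild-type and 9.47 in untreated knockout cells, and 11.53 and 11.56 with curdlan; cell cycle genes averaged 9.39, 8.55, 8.56 and 7.88 in the same order.

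Genes next to Il2 were compared because a knockout made in another strain can carry donor alleles around the gene. Of the 100 tested genes nearest Il2, 50 on either side on chromosome 3, 10 passed in the averaged genotype contrast (10%), against 5.02% of all other genes (odds ratio 2.1, 95% interval 0.97 to 4.07, Fisher's exact p 0.0348, two-sided). They were Gnb4 (-0.36), Mccc1 (-0.41), Exosc9 (-0.21), Ccna2 (-1.17), Cetn4 (-0.67), Spry1 (-1.14), Ankrd50 (-0.38), Plk4 (-0.52), Slc7a11 (0.17) and Trpc4 (-0.31). With a random culture block 7 passed and the call was lost (Fisher's exact p 0.0862), while the odds ratio stayed alike (2.14). In untreated cells 6 of the 100 passed (odds ratio 4.51, 95% interval 1.6 to 10.3, Fisher's exact p 0.00304) and in curdlan-treated cells 5 (odds ratio 8.79, 95% interval 2.74 to 21.82, Fisher's exact p 0.000389). Fisher's test counts genes as independent, but all calls come from the same cultures and many genes move together. Its p-values and intervals carry no spread between cultures and can be too small and too narrow.

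**Figure D4:**
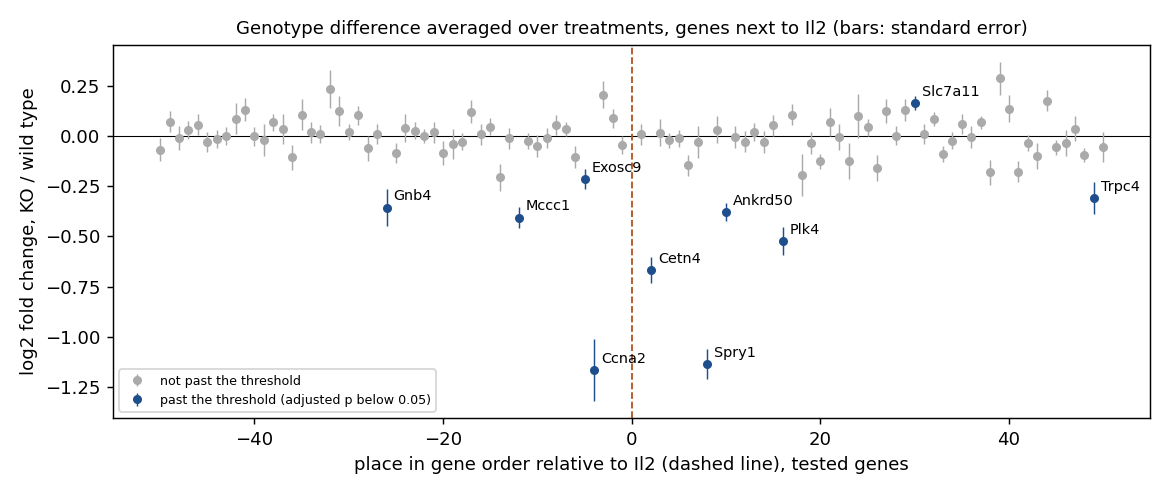
Averaged genotype effect (log2 fold change, knockout minus wild type) of the 50 tested genes on either side of Il2 in chromosome order, with SE bars and genes past the threshold marked. Spry1 (-1.14) and Ccna2 (-1.17) were lowest.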

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

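Of the tests in this part, the ceiling test, the test of donor alleles and the splits were planned, and the tests of single cultures, sex composition, precursors, spread between cultures and cell cycle neighbours were chosen only after the result was seen.

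Camera's test of the interaction called 8 lists as differing between genotypes in their response to curdlan. The mean difference was -0.273 for interferon-stimulated genes, -0.145 for IL-2 and common gamma chain signalling, -0.144 for inflammatory cytokines, -0.092 for cholesterol synthesis, -0.091 for NRF2 targets, -0.075 for immediate early genes, -0.054 for ribosomal proteins and 0.158 for the cell cycle. The IL-2 signalling list holds Il2 itself, whose own difference was -1.89 and made up most of the difference of the list. With 1 array or culture left out, cytokines ranged from -0.231 (without knockout culture 1) to -0.004 (knockout culture 3). The cell cycle ranged from 0.003 to 0.335 (wild-type curdlan-treated arrays 1 and 2), cholesterol synthesis from -0.151 to -0.042 (knockout curdlan-treated arrays 3 and 2) and immediate early genes from -0.114 to -0.034 (wild-type untreated array 1 and curdlan-treated array 1). The mean nearest 0 was -0.084 for IL-2 signalling (without knockout curdlan-treated array 3), -0.041 for NRF2 targets (knockout untreated array 1), -0.036 for ribosomal proteins (wild-type curdlan-treated array 2 or knockout untreated array 1) and -0.107 for interferon-stimulated genes (knockout curdlan-treated array 3). With an estimated correlation 0 of these 8 passed.

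Interferon-stimulated genes rose less in knockout cells, from a higher untreated level (9.47 ± 0.20 against 9.17 ± 0.04, SD, n = 3, exact permutation p 0.1) to nearly the same treated level (11.56 against 11.53, exact permutation p 0.8). A single culture remains open, since the mean difference without knockout culture 3 was -0.154 (SE 0.075), near -0.136, the bound at 50% of the full value, and -0.107 without its curdlan-treated array alone. A signal ceiling remains open too, since the dimmer members gave -0.231 ± 0.107 (SE, 14 genes), within their spread of that bound. The brighter members gave -0.314 ± 0.064 (SE, 14 genes). The highest group mean of a gene was 12.34 among the dimmer and 13.09 among the brighter members, while the highest array value was 14.04. Ordinary spread between cultures is consistent with the data: the rises were 2.43, 2.30 and 2.35 in wild-type and 2.30, 2.11 and 1.85 in knockout cultures (exact permutation p 0.2). Sex composition also remains open for the higher untreated level. The interferon-stimulated genes called there, Rtp4, Ifit1, Oasl2 and Rsad2, lost their call with the sex-linked level as a covariate. Untreated levels were 9.12, 9.18 and 9.20 in wild-type and 9.34, 9.70 and 9.38 in knockout cultures 1, 2 and 3. Without knockout culture 2, which had both Xist and Y-linked signal, the difference was 0.187 instead of 0.302, with the camera call kept. A higher interferon tone in resting cells without IL-2 is a biological explanation that was not tested apart from genotype.

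Cell cycle genes were lower in knockout cells in the averaged contrast (mean -0.76), though the list did not pass with an estimated correlation. Per culture, the exact permutation p was 0.1 untreated and 0.1 with curdlan, the smallest possible. A single culture as the whole cause is argued against, since the list stayed at -0.606 without wild-type culture 2, beyond 50% of the full value (-0.382). The SE of that value, 0.051, is over genes and holds no spread between cultures. With the sex-linked level as a covariate the list stayed at -0.726. The covariate, a log2 mean, put untreated knockout culture 2 (7.91) nearer culture 3 (9.24) than 1 (4.65), against a linear Y-linked share of 0.384. With low Xist, the list mean was 9.178 untreated and 8.252 with curdlan in wild-type culture 1, against 8.742 and 7.981 in knockout culture 3. With high Xist, it was 9.665 and 9.32 in wild-type cultures 2 and 3 against 8.489 in knockout culture 1 untreated. With curdlan these were 8.916 and 8.516 against 7.831. So few cultures leave sex composition open as part of the cause. Fewer dividing myeloid precursors among the knockout cells cannot be told apart from slower division: 18 precursor markers had a median of -0.054 (SE 0.093) against -0.371, which is 50% of the list's median, but 12 dim markers set that median and 8 of the 18 are in other lists. The 6 above the median level of all genes had a median of -0.568, with 5 below 0. Past the threshold were 2, Cd34 (-1.42, adjusted p 0.00619) and Kit (-0.54, adjusted p 0.0394), while Flt3 was at 0.05. Whether the selection for CD11c removed such cells was not tested. An effect of IL-2 on division stays among the open explanations and was not tested further.

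Of the 100 genes next to Il2, 10 passed in the averaged genotype contrast. Alleles of the donor strain kept around the disrupted gene are a candidate explanation, with an enrichment at Fisher's exact p 0.0348, although its 95% interval for the odds ratio included 1 (0.97 to 4.07), as it did with a random culture block (0.83 to 4.6, Fisher's exact p 0.0862). The intervals lay above 1 in untreated (1.6 to 10.3) and in treated cells (2.74 to 21.82), with 6 and 5 genes. Genes are not independent replicates, so these intervals and p-values describe the share and do not settle the cause. Cell cycle genes that happen to lie there remain open as part of the enrichment, since the odds ratio was 1.95 (Fisher's exact p 0.0607) without the cell cycle list. That step left 99 neighbours with 9 called, and genes outside the list were kept whatever their function. The tests in untreated and in treated cells were not repeated without the list. No test here separates donor variants that change the genes from those that change the match to the probes, or from a response of neighbours such as Spry1 to the loss of IL-2.

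Probe sets outside the gene comparisons also passed when fitted in the same way. With several symbols, 126 of 1321 (9.5%) passed for curdlan in wild-type cells, 155 (11.7%) in knockout cells and 29 (2.2%) for the averaged genotype effect. Of the 11799 not listed in the probe table, 507 (4.3%), 847 (7.2%) and 79 (0.7%) passed.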

How the results depend on the processing

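The fixed culture block, the sex-linked covariate and the runs without a culture were chosen after seeing the data. The other alternatives were planned.

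No named gene reversed under any alternative: 9614 repeats of a call kept it and 1609 lost it, most with an array or a culture left out. Part of this was fixed in advance. Where the arrays of the groups did not overlap, leaving out an array or a culture cannot reverse the sign. Leaving out an array outside a contrast leaves its log2 fold change unchanged. For called lists, 1638 repeats kept the call, 186 lost it and 5 reversed. The cell cycle interaction went from 0.158 to -0.096 with array weights, and the receptor list in untreated cells went to -0.001 without wild-type replicate 2 and -0.007 without wild-type replicate 3, for an untreated array or a culture, in a range up to 0.09 over arrays and cultures. The cause was not tested.

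A log2 fold change of at least 1 as well left 348 and 261 genes for curdlan in wild-type and knockout cells, and 85, 23 and 65 for genotype in untreated cells, treated cells and the average, by its construction. Array weights gave 615, 1402 and 2186 for these genotype contrasts, and the replicate block over all arrays gave 699, 450 and 1621. Arrays with the same number in different genotypes correlated at 0.22, 0.11 and 0.25 untreated, against -0.28 to 0 for other numbers, and at 0.17, -0.13 and 0.33 with curdlan, against -0.30 to 0.21. Deviations from a group mean cancel within the group, so part of the contrast with other numbers is built in. Whether the numbers go together across genotypes is therefore not settled in untreated cells, and 1 treated pair went the other way (-0.13). Besides the untreated count, that block ended the calls of Vpreb3 for curdlan in knockout cells and of the NF-kB list in untreated cells. The sex-linked covariate gave 164 in untreated cells, the filter on dim genes 197 in treated cells, and a fit of only the arrays compared 70 and 15, with fewer samples. The cause of the other shifts was not tested. The random and fixed culture blocks left each total gene count within 1.5 times, though the random block gave 3080 higher genes for curdlan in knockout cells and 149 for the averaged genotype effect. The random block ended the calls of 17 named genes in the averaged contrast, such as Iigp1, and the fixed block that of Mmp8 in knockout cells.

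With an estimated correlation 0, 0, 1, 0, 1 and 0 lists passed in the order of curdlan in wild-type cells, in knockout cells, genotype untreated, treated, averaged, and interaction. The list kept was conventional dendritic cells. Fry gave 24 for curdlan in knockout cells, 2 and 2 for genotype untreated and treated, 7 averaged and 0 for the interaction. The dim filter gave 5 lists for genotype in untreated cells and 5 for the interaction, with fewer genes tested. The correlation of the responses was 0.952 over genes past the threshold in either genotype and 0.955 without dim genes.

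Leaving out an array or a culture gave 1841 to 4011 genes for curdlan in wild-type cells, 1079 to 5284 in knockout cells, 9 to 608 for genotype untreated, 18 to 299 treated, 325 to 1431 averaged and 0 to 3 for the interaction. Lists ranged from 13 to 18, 14 to 17, 6 to 12, 8 to 15, 7 to 12 and 4 to 9, and the correlation from 0.867 to 0.926. Dim genes lie near background, where a change is understated; Il2 in untreated cells, at 5.49, lies under the median gene mean of 6.96.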

Other observations

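The splits of the samples were planned. The sex-linked values were planned as values, and the mixture of knockout culture 2 was examined only after they were seen.

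Sex-linked genes differed between cultures. Wild-type culture 1 and knockout culture 3 had low Xist (5.46 and 5.63, and 4.91 and 5.18, untreated and with curdlan) and high Eif2s3y, a Y-linked gene (9.67 and 9.39, and 9.99 and 9.87). Wild-type cultures 2 and 3 and knockout culture 1 had high Xist and low Eif2s3y. Knockout culture 2 had both: Xist was 12.14 and 11.91 and Eif2s3y 8.72 and 8.41. Against the other cultures on the linear scale, its Y-linked signal was 0.384 and 0.35 of the level in male-type cultures, and its Xist signal 0.706 and 0.696 of that in female-type cultures.

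Every contrast of 3 arrays against 3 allows 10 splits, too few for a share under 0.05. Every other split mixes the real groups, so a real difference enters the spread within its groups and lowers its gene count. A low count in the other splits is therefore no measure of what arises without an effect. The real split gave 3899 genes for curdlan in wild-type cells (highest other 0), 4481 in knockout cells (highest other 0), 283 for genotype in untreated cells (highest other 0), 124 in treated cells (highest other 2), 1005 averaged (highest other 671, wild-type culture 1 with knockout cultures 1 and 2 against the rest) and 0 for the interaction (highest other 0). As many genes came from 1, 1, 1, 1, 1 and 10 of the 10 splits in this order. For lists the real and highest other values were 15 and 14, 14 and 18, 8 and 9, 8 and 11, 11 and 14, and 8 and 3, and 1, 2, 5, 4, 4 and 1 of the 10 splits gave as many. Among splits of the curdlan contrasts that part all 3 culture pairs, the other 3, which also mix treated and untreated arrays, gave 0 genes each in wild-type and in knockout cells. They gave 6, 7 and 13 lists in wild-type and 13, 9 and 7 in knockout cells.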
